A study of Mus musculus with 3 samples.

How the data were processed

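Messenger RNA was sequenced from 3 libraries of 1 sorted bone marrow population of C57BL/6 mice. Per the labels' protocols, marrow was taken from tibiae and femurs by light crushing, cells were sorted into Trizol, and libraries were made with a NEXTflex kit for mRNA and read on a NextSeq500 sequencer. The labels gave 1 group, with no control population and no treatment. Replicate numbers were those of the labels. The labels gave n = 3 and did not say whether each library came from its own mouse. The p-values of tests over libraries thus measure only the spread between these libraries, which may be technical. Those of tests over genes, such as the list tests, measure no spread between libraries.

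The deposited values were CPM, the reads of a gene per 1000000 assigned reads, for each gene and library. The authors' tools, per the submitters' processing notes, were FastQC, STAR, featureCounts and edgeR, with the genome builds mm10 and GRCh38. Tool versions, the role of each build, the annotation, the strand setting of the counting and the gene filter were not given in the sources used here. All gene identifiers in the files were mouse Ensembl identifiers. Each file held 11463 entries, of which 44 repeated a gene with identical values under another Entrez identifier. After each gene was kept once, 11419 genes remained and the CPM of each library summed to 1000000, so the CPM was relative to reads assigned to the listed genes, with no scaling between libraries beyond that. Of the listed genes, 160 were at 0 in all 3 libraries, so the list had not been chosen on these 3 libraries alone. A gene outside the list is called not listed here, and its level is unknown.

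Every value was a whole multiple of the CPM of 1 read, within a tolerance of 0.01 reads, in 100% of the values of each library. The recovered totals were 5150020 reads in replicate 1, 40149274 in replicate 2 and 37604930 in replicate 3. At 10 CPM a gene thus had 51.5 reads in replicate 1, 401 in replicate 2 and 376 in replicate 3. A count of 0 allows up to 3 reads, or 0.583, 0.0747 and 0.0798 CPM in replicates 1, 2 and 3. These limits cover counting error only, since reads without molecular identifiers are not independent molecules.

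The tests, the 26 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. With 1 group, each gene was compared with a fixed level of 10 CPM. An edgeR quasi-likelihood test had been written for counts, with limma as the test for CPM. Because the deposited unit was CPM, limma 3.58.1 in R 4.3.3 was the test reported. An intercept was fitted to log2(CPM + 1), where 1 is the pseudocount, and tested against log2 of 10 CPM plus the same pseudocount, two-sided, with empirical Bayes moderation. The moderation followed the trend of variance with level, a choice made after the unit was known. Genes with at least 10 recovered reads over the libraries entered (11123 genes), p-values were adjusted by the method of Benjamini and Hochberg, and a gene was called above or below 10 CPM at an adjusted p under 0.05. A difference on the log2(CPM + 1) scale understates that of low genes.

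The 26 lists held 343 genes, of which 273 were listed in the files and 70 were not. The lists that lost most were T and NK (12 of 16 not listed), stromal and endothelial (10 of 15) and plasma cell (7 of 10). The shares of these lists thus rest on few members. For each list the number of members above 10 CPM was compared with that of all other listed genes by Fisher's exact test, two-sided, adjusted over the 26 lists. Genes are the units of that test, not replicates. The percentile of the list's median level among 10000 random lists of equal size was also computed. The 3 macrophage lists (core macrophage, complement and efferocytosis, erythroblastic island and iron recycling) were pooled and set against 5 other lineage lists by the difference of median log2(CPM + 1), with 100000 permutations of list membership over genes. Per library, the same difference was tested with the exact two-sided sign-flip permutation test, whose smallest possible p with 3 libraries is 0.25. Spread between libraries was measured as the common biological coefficient of variation in edgeR 4.0.16, correlations over genes, and a chi-square of recovered reads over genes with at least 20 reads in a pair.

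Named genes were the 4 genes of the sort gate; the 20 genes of highest mean CPM, leaving out mitochondrially encoded, ribosomal protein, numbered Gm and Rn genes; in each list up to 4 members of highest mean among those above 10 CPM and up to 2 of lowest mean among those below; the 10 genes with a mean of at least 10 CPM and the largest range over libraries; and Xist with Ddx3y, Eif2s3y, Kdm5d and Uty as a check of sex. Of the genes this rule takes, 1 is not reported here. Gene lengths and coordinates came from the GENCODE annotation of GRCm38, the same assembly as mm10. Of the 11419 genes, 99.9% had a length there. The 4 haemoglobin genes and the Ear genes have near-identical copies between which the authors' counting could split reads, so their single levels are uncertain, as are those of overlapping and antisense genes.

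Alternatives were DESeq2 size factors, no filter, the edgeR filter filterByExpr, DESeq2 1.42.0 as the test on recovered reads, reference levels of 5 and 20 CPM, a pseudocount of 0.1, CPM per kb of gene, the tested genes as background, list means, list members with at least 10 reads, library sizes without mitochondrial, haemoglobin and immunoglobulin genes, and each library left out. For CPM per kb the level was 2.33, at the rank of genes that 10 CPM has. The edgeR test on the recovered reads, TMM scaling, a pseudocount of 0.1 in the test of every gene, and library sizes without ribosomal DNA genes or without the late neutrophil list were added after seeing the data. In edgeR the F statistic was formed from the deviances of the fit, because its own function has no null model for a lone intercept. In DESeq2 dispersions were estimated before the reference level entered the size factors. On simulated reads for 11087 genes, the limma test called 100% of 50 genes set at 4-fold and of 50 at 2-fold the level, 92% of 50 at 0.5-fold, 100% of 50 at 0.25-fold and 1.5% of 200 set at the level. For the same folds edgeR called 100%, 100%, 76%, 100% and 5%, and DESeq2 100%, 100%, 88%, 100% and 3%. The genes set at these folds were drawn from a negative binomial with the dispersion of the trend at their level. Spread of single genes around that trend and added zeros were not simulated for them. The permutation test over genes called 5.5% of 200 simulated contrasts with no shift and 82% of 200 with a shift of 3 on the log2 scale. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.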

Results

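The study profiled messenger RNA in a myeloid population sorted from hind limb marrow of C57BL/6 mice, an inbred strain. The gate took cells positive for CD11b, F4/80 and CD169 and negative for CX3CR1, and the study's design text puts the word macrophages for them in quotation marks. CD169 (sialoadhesin, gene Siglec1) is a surface receptor of resident marrow macrophages, and CX3CR1 is a chemokine receptor of monocytes and some macrophages. There were 3 libraries of this 1 population, with 5150020, 40149274 and 37604930 reads assigned to the listed genes in replicates 1, 2 and 3. Without a second population, the data allow a description of which genes were above or below a fixed level, which cell type genes stood out, and how far the libraries differed.

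Of the genes that define the gate, the RNA of Itgam and Adgre1 was above 10 CPM and that of Siglec1 and Cx3cr1 was below. Itgam, which encodes CD11b, was at 503 ± 55.1 CPM (SD, n = 3), a log2 level of 5.51 over 10 CPM (SE 0.10, limma adjusted p = 3.47e-22). Adgre1, which encodes F4/80, was at 22.2 ± 3.97 CPM (log2 1.06 over 10 CPM, SE 0.18, limma adjusted p = 9.85e-06). Siglec1 was at 2.87 ± 2.20 CPM (log2 level -1.74, SE 0.35, limma adjusted p = 9.58e-05), with 2 reads in replicate 1, 147 in replicate 2 and 172 in replicate 3. Cx3cr1 was at 0.141 ± 0.244 CPM, with 17 reads in replicate 2 and 0 reads in the others, which allows up to 0.583 CPM in replicate 1 and 0.0798 CPM in replicate 3. Its call below 10 CPM had an adjusted p of 4.18e-08 in limma and was lost in edgeR on recovered reads (adjusted p = 0.0518). The genes lie on GRCm38 chromosome 7 (128062640 to 128118491, plus strand, Itgam, ENSMUSG00000030786), chromosome 17 (57358691 to 57483527, plus strand, Adgre1, ENSMUSG00000004730), chromosome 2 (131069220 to 131086765, minus strand, Siglec1, ENSMUSG00000027322) and chromosome 9 (119901616 to 120069879, minus strand, Cx3cr1, ENSMUSG00000052336). All 4 are protein-coding and the intervals span whole genes.

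Within each library, Itgam exceeded Cx3cr1 by 8.80 ± 0.42 on the log2(CPM + 1) scale, Adgre1 by 4.35 ± 0.12 and Siglec1 by 1.55 ± 1.01 (SD, n = 3). Each ratio was positive in 3 of 3 libraries, with an exact sign-flip permutation p of 0.25, the smallest that 3 libraries allow. Cx3cr1 had 0 reads in replicates 1 and 3, so no ratio could be negative there. The sign count and its p thus do not test the gate. For Siglec1 the ratio in replicate 1 (0.47) rested on 2 reads against 0. Siglec1 at 0.388 CPM there lay under the 0.583 CPM that a count of 0 allows, so the sign of that ratio is undetermined. With a pseudocount of 0.1 the ratios to Cx3cr1 were 11.49 for Itgam, 6.99 for Adgre1 and 3.56 for Siglec1, by the smaller pseudocount under a gene near 0.

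**Figure D1:**
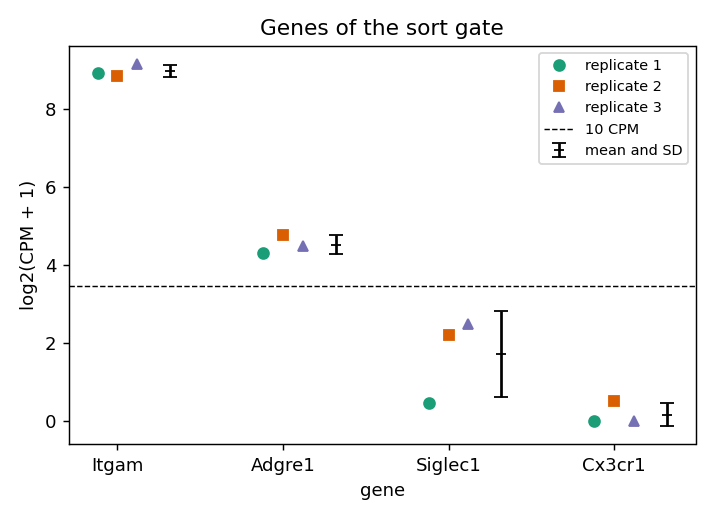
Level of the 4 genes of the sort gate, as log2(CPM + 1), in each of the 3 libraries (points), with the mean and SD beside them and a dashed line at 10 CPM. Itgam (503 CPM) and Adgre1 (22.2 CPM) lie above the line, Siglec1 (2.87 CPM) and Cx3cr1 (0.141 CPM) below it.

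Genes of the late neutrophil list were the 4 most abundant of the named genes. Ngp, which encodes neutrophilic granule protein, was highest at 55067 ± 4306 CPM, followed by S100a9 (45313 ± 7554), S100a8 (34578 ± 7768) and Ltf (28909 ± 458), which encode the calprotectin subunits and lactoferrin (SD, n = 3). Camp, the cathelicidin gene, was at 16571 ± 3174 CPM and Lcn2, the lipocalin 2 gene, at 14336 ± 891. Together these 6 genes took 19.5 ± 2.10% of all assigned reads. Among the 20 highest genes that the naming rule takes were also Lyz2 (14339 ± 694), which encodes lysozyme in myeloid cells, Chil3 (5741 ± 378), Mmp9 (5116 ± 134), Cd177 (4924 ± 133), Retnlg (3321 ± 496) and the complement gene C3 (3317 ± 453). The others were Actb at 18850 ± 787 CPM, Flna at 4270 ± 502, Tmsb4x at 3784 ± 408, Lcp1 at 3362 ± 596, Myh9 at 3298 ± 894, Pfn1 at 3273 ± 287, Arhgdib at 5242 ± 606 and Tkt at 3228 ± 261. All 20 were above 10 CPM in the limma test.

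Of 11123 genes tested, 6539 were above 10 CPM, 3153 were below and 1431 were called neither way (limma, adjusted p under 0.05). At an unadjusted p under 0.05 the counts were 6562 and 3173. The median over all listed genes was 19.7 CPM, and 57.3% of them were above 10 CPM. Without replicate 1, the shallowest library, 6537 genes were above and 3109 below. On the recovered reads edgeR called 6655 above and 2729 below, and DESeq2 called 6568 and 2951. With the level set at 5 CPM, 7712 genes were above and 1870 below. Calls below 10 CPM that edgeR did not give, among the named genes, were those of Cx3cr1, Marco, Pros1, Palld, Prdm1, Batf3, Zbtb46, Pf4, Ifi44, Fosb, Il1a, Ccl4, Pdcd1lg2, Cxcl16, Gm10717 and Uty.

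The genes of both neutrophil lists stood above 10 CPM without exception. All 16 late neutrophil genes were above, with a median of 4123 CPM (Fisher's exact adjusted p = 0.00208 over 26 lists), and the list took 21.5 ± 2.06% of reads. All 10 primary granule genes, which are made by promyelocytes, were above as well, with a median of 532 CPM (Fisher's exact adjusted p = 0.0290). Mpo, the myeloperoxidase gene, was at 3193 ± 474 CPM, Elane, the neutrophil elastase gene, at 1694 ± 273, Fcnb at 1193 ± 92.8 and Prtn3, the proteinase 3 gene, at 901 ± 152 (SD, n = 3). Both list medians lay at percentile 100 of those of 10000 random gene lists of equal size. For every list given here and in the following paragraphs, the counts above and below 10 CPM were the same when adjusted over the list alone. With the level at 5 CPM the primary granule list kept 100% of members above and its adjusted p was 0.0822, as more of the other genes were above too.

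Proliferation genes and lysosome genes were the other lists with a higher share than the rest. All 18 proliferation genes were above 10 CPM (median 121 CPM, Fisher's exact adjusted p = 0.00127), among them Mki67 at 668 ± 166 CPM and Top2a at 499 ± 74.2, which mark cycling cells, Mcm5 (247 ± 31.3) of the replicative helicase and Rrm2 (216 ± 18.5) of ribonucleotide reductase. Of 17 lysosome genes, 15 were above and 1 below (median 157 CPM, Fisher's exact adjusted p = 0.0385). Psap, the prosaposin gene, was at 909 ± 35.8 CPM, Grn, the progranulin gene, at 444 ± 22.1, Ctsd, the cathepsin D gene, at 425 ± 40.4 and Cd63 at 357 ± 38.8, while Ctsl, the cathepsin L gene, was below at 5.79 ± 1.48. Per kb of gene the lysosome share was 82.4% and no longer passed the test against the other genes (adjusted p = 0.0929), as at 5 CPM (88.2%, adjusted p = 0.137).

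Macrophage genes were split. Of 15 core macrophage genes, 4 were above 10 CPM, 7 below and 4 not called, with a median of 4.22 CPM (percentile 1.17 of random lists), and their share above did not pass the test against the other genes (26.7% against 57.3%, Fisher's exact adjusted p = 0.0502). Folr2, at 0.0747 CPM, had too few reads to be tested and was counted as not called. Sirpa, an inhibitory receptor of myeloid cells in general, was at 490.5 ± 72.8 CPM and Mpeg1, the perforin-2 gene, at 225 ± 74.2. Csf1r, the receptor for the macrophage growth factor CSF1, was at 55.1 ± 13.8 CPM and Cd68, a lysosomal membrane protein of macrophages, at 44.7 ± 5.58. Fcgr1, the gene of the high-affinity Fc receptor CD64, was below at 1.36 ± 1.18 CPM, as was Clec4n at 0.844 ± 0.399 (SD, n = 3). With DESeq2 size factors or TMM scaling the adjusted p of this list came to 0.049999 and 0.0499, so the list lies at the threshold.

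Complement and efferocytosis genes, which resident macrophages use to take up dying cells, were lower than the rest, with 3 of 14 above 10 CPM, 8 below and a median of 1.62 CPM (Fisher's exact adjusted p = 0.0385). Above were C1qa at 18.7 ± 7.91 CPM, Itgav at 18.7 ± 5.26 and Axl at 16.8 ± 5.55, and all 3 lost their call without replicate 2 (limma adjusted p = 0.0925, 0.104 and 0.158). Marco (0.141 ± 0.244) and Pros1 (0.400 ± 0.389) were below in limma but not in edgeR on recovered reads (adjusted p = 0.0518 and 0.0594), and Mertk was below at 1.01 ± 0.537 CPM, a gene chosen after its values were seen. The list's call was lost without replicate 3 (35.7% above, adjusted p = 0.339), at 5 CPM (35.7%, 0.0689) and per kb of gene, where the share stayed at 21.4% (adjusted p = 0.0715), and without replicate 2 the share was 0%.

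Of 14 genes of erythroblastic islands and iron recycling, the functions by which marrow macrophages nurse erythroblasts and return iron from red cells, 8 were above 10 CPM and 5 below (median 28.2 CPM, Fisher's exact adjusted p = 1.0). Tcn2, which encodes transcobalamin 2, was at 419 ± 26.1 CPM, Slc40a1, the iron exporter ferroportin, at 184 ± 9.45, Slc48a1, a haem transporter, at 107 ± 14.6 and Hmox1, haem oxygenase 1, at 96.1 ± 23.2. Trf (1.51 ± 0.609) and Palld (2.03 ± 1.81) were below. Vcam1, an adhesion molecule of island macrophages, was at 74.3 ± 19.3 CPM, and Spic, a transcription factor of iron-recycling macrophages, at 2.54 ± 1.01, both chosen after their values were seen.

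When the 3 macrophage lists were pooled (43 genes, 15 above and 20 below 10 CPM, median 6.69 CPM), their median lay far under those of both neutrophil lists. The log2 difference of medians was -9.10 to the late neutrophil list and -6.14 to the primary granule list, corresponding to 548-fold and 70.4-fold higher neutrophil medians on the log2(CPM + 1) scale. Both had a permutation p over genes of 1e-05, the smallest that the permutations can give, and an adjusted p of 2.5e-05 over 5 contrasts. The direction was the same in 3 of 3 libraries, with differences of -9.33 ± 0.20 and -6.31 ± 0.09 (SD, n = 3, exact sign-flip permutation p = 0.25 for each). The pooled median could not be distinguished from those of the monocyte list (0.56, permutation adjusted p = 0.831), the erythroid list (-0.61, adjusted p = 0.831) or the B lymphoid list (0.82, adjusted p = 0.714). Over libraries these differences were 0.28 ± 0.51, -0.79 ± 0.46 and 0.59 ± 0.78, with exact sign-flip permutation p of 0.5, 0.25 and 0.5.

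Fewer monocyte genes than other genes were above 10 CPM, with 2 of 13 above, 6 below, 5 not called and a median of 3.98 CPM (Fisher's exact adjusted p = 0.0167). Vcan, at 0 CPM in every library, was not tested and was counted as not called. Ly6c2, a surface antigen of classical monocytes that granulocyte precursors also carry, was at 1030 ± 105 CPM and Treml4 at 18.3 ± 3.77, while Ace (0.528 ± 0.789) and Cd300e (0.596 ± 0.329) were below. The call of the monocyte list was lost with the level at 5 CPM (38.5% above, adjusted p = 0.0822). Treml4 lost its call without replicate 2 (limma adjusted p = 0.0768), which left 7.69% of the list above.

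Transcripts of eosinophils and basophils were present above 10 CPM, although neither list's share passed the test against the other genes. Of 10 eosinophil genes, 8 were above and 1 below (median 60.4 CPM, Fisher's exact adjusted p = 0.333), with Prg2, the major basic protein gene, at 511 ± 203 CPM, Epx, eosinophil peroxidase, at 155 ± 108, Ear2 at 138 ± 35.9, Alox15 at 100.4 ± 35.6 and Il5ra below at 3.44 ± 1.30. Of 6 basophil and mast cell genes, 4 were above and 1 below (median 65.7 CPM, Fisher's exact adjusted p = 1.0), and the list's median was 151 CPM in replicate 1, 22.1 in replicate 2 and 23.8 in replicate 3. Hdc, histidine decarboxylase, was at 612 ± 61.7 CPM. The basophil proteases differed between libraries, with Prss34 at 596, 74.5 and 81.2 CPM and Mcpt8 at 259, 35.4 and 37.4 CPM in replicates 1, 2 and 3, and Cyp11a1 was below 10 CPM at 3.67 ± 3.47. Cpa3 was above (43.7, 8.77 and 10.1 CPM, limma adjusted p = 0.0477), but without replicate 1 its log2 level was -0.079 (adjusted p = 0.773), and with DESeq2 size factors or TMM scaling its call was lost too (0.0836 and 0.0758), which left 50% of the list above.

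Of the red cell and lymphoid lists, the B lymphoid list had a lower share above 10 CPM than the other genes, and the erythroid, T and NK and plasma cell lists did not pass the test. Of 18 erythroid genes, 8 were above and 8 below 10 CPM (median 10.5 CPM, Fisher's exact adjusted p = 0.467), with the globin genes Hbb-bs at 321 ± 123 CPM, Hba-a1 at 137 ± 66.0, Hba-a2 at 99.1 ± 39.3 and Hbb-bt at 72.8 ± 27.0, and Rhag (1.72 ± 1.31) and Tspo2 (2.31 ± 0.733) below. The 4 haemoglobin genes took 0.0917%, 0.0506% and 0.0465% of reads in replicates 1, 2 and 3. B lymphoid genes had 1 of 13 members above and 9 below (median 3.32 CPM, Fisher's exact adjusted p = 0.00251), the exception being Ighm, the immunoglobulin mu chain, at 200.2 ± 20.6 CPM, with Ms4a1 at 1.23 ± 0.408 and Ebf1 at 2.26 ± 0.732. Per kb of gene the B lymphoid share was 38.5% (adjusted p = 0.437). Of 4 listed T and NK genes, Nkg7 was above at 87.6 ± 17.5 CPM and 3 were below, among them Cd4 (1.09 ± 1.29) and Gzma (3.42 ± 1.35) (Fisher's exact adjusted p = 0.462). Plasma cell genes had 0 of 3 listed members above and 2 below, Irf4 (1.21 ± 0.685) and Prdm1 (0.0996 ± 0.173) (Fisher's exact adjusted p = 0.169).

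Dendritic and stromal genes were also lower than the rest. None of 7 dendritic and plasmacytoid genes was above 10 CPM and all 7 were below (median 1.17 CPM, Fisher's exact adjusted p = 0.0167), with Batf3 at 0.141 ± 0.244 CPM and Zbtb46 at 0.448 ± 0.490, whose calls were lost in edgeR on recovered reads (adjusted p = 0.0518 and 0.0652). The call of the dendritic list was lost per kb of gene (14.3% above, adjusted p = 0.130) and with the level at 20 CPM (0%, 0.0712). Of 5 listed stromal and endothelial genes, 0 were above and 3 below (median 0.837 CPM, Fisher's exact adjusted p = 0.0411), including Pdgfrb (0.837 ± 0.571) and Cxcl12 (2.68 ± 1.77), and this call was lost without replicate 2 (adjusted p = 0.0772), without replicate 3 (0.0605), against the tested genes alone (0.165), per kb of gene (0.0770) and at 20 CPM (0.214). Osteoclast genes had 1 of 5 above, Nfatc1 at 121 ± 28.5 CPM, with Tnfrsf11a (0.475 ± 0.416) and Ocstamp (0.158 ± 0.273) among 4 below (Fisher's exact adjusted p = 0.297). Megakaryocyte and platelet genes had 1 of 7 above, Itgb3 at 98.9 ± 16.8 CPM, with Pf4 (1.04 ± 1.79) and Vwf (2.25 ± 2.35) among 5 below (Fisher's exact adjusted p = 0.111). Stem and progenitor genes had 1 of 6 above, Kit at 65.6 ± 6.73 CPM, with Meis1 (1.37 ± 1.08) and Ly6a (2.90 ± 1.03) among 3 below (Fisher's exact adjusted p = 0.180), and without replicate 3 the share above was 33.3% in place of 16.7%.

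**Figure D2:**
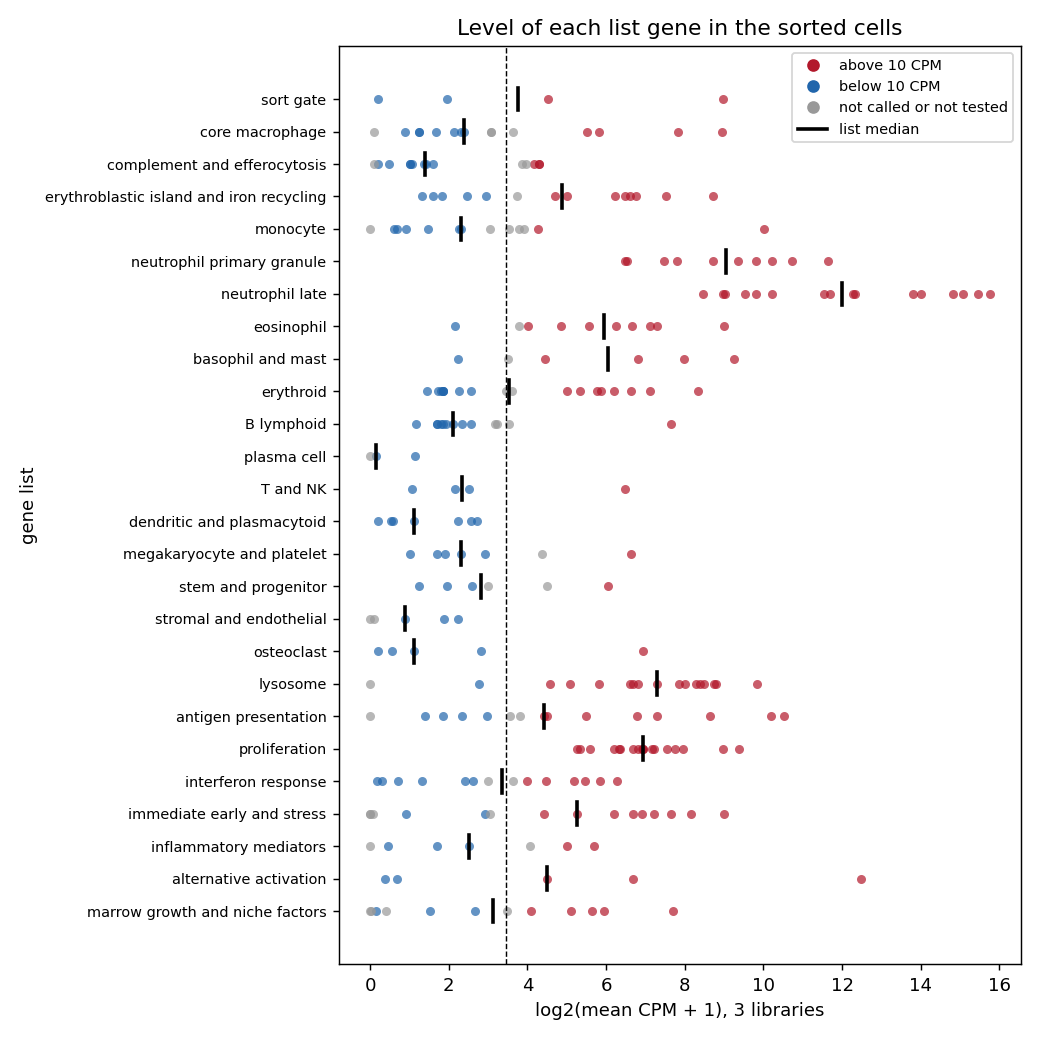
Mean level of each listed gene over the 3 libraries, as log2(mean CPM + 1), for the 26 gene lists (1 point per gene, coloured by its call against 10 CPM, dashed line), with the list median as a black bar. The late neutrophil list (median 4123 CPM) and the primary granule list (median 532 CPM) lie to the right of the core macrophage list (median 4.22 CPM).

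For function lists other than lysosome and proliferation, the share above 10 CPM did not pass the test against the other genes. Antigen presentation genes had 8 of 15 above and 4 below (Fisher's exact adjusted p = 0.988). Above were H2-D1 at 1467 ± 68.6 CPM, B2m at 1161 ± 109 and H2-K1 at 397 ± 28.1, which encode class I chains, and the peptide transporter Tap2 at 157 ± 12.6. Class II genes above 10 CPM, chosen after their values were seen, were Cd74 at 44.1 ± 6.39 CPM, H2-Ab1 at 21.4 ± 2.22 and H2-Aa at 20.3 ± 5.19, while H2-Eb1 (13.1 ± 4.23) and H2-DMa (10.8 ± 4.63) were not called and H2-DMb1 (6.81 ± 2.66) was below. Ciita, the activator of class II genes, was below at 1.62 ± 0.119 and the costimulatory gene Cd86 at 2.61 ± 1.35. Interferon response genes had 6 of 14 above and 6 below (adjusted p = 0.447 by Fisher's exact test), with Irf7 at 56.6 ± 5.36 CPM, Oasl2 at 42.7 ± 16.9 and Rsad2 at 35.6 ± 7.33, and with Ifi44 (0.124 ± 0.215) and Mx2 (0.239 ± 0.415) below.

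Immediate early and stress genes had 9 of 15 above and 2 below (Fisher's exact adjusted p = 1.0), with Zfp36 at 514 ± 91.9 CPM, Ier2 at 285 ± 50.4, Junb at 201 ± 9.0 and Btg2 at 149 ± 8.70, and Atf3 at 0.876 ± 0.257. Fosb differed between libraries, at 19.2, 0.249 and 0.106 CPM in replicates 1, 2 and 3, and its call below 10 CPM was lost in edgeR (adjusted p = 0.467) and DESeq2 (adjusted p = 0.754). Inflammatory mediators had 2 of 7 above, the cytokine genes Il1b (50.9 ± 13.9 CPM) and Tnf (31.3 ± 3.72), with Il1a (0.367 ± 0.390) and Ccl4 (2.27 ± 2.83) among 3 below (Fisher's exact adjusted p = 0.270). Of 5 alternative activation genes, Chil3, Il4ra (102 ± 20.1) and Mgl2 (21.6 ± 5.49) were above and Clec10a (0.595 ± 0.219) and Pdcd1lg2 (0.294 ± 0.291) below (Fisher's exact adjusted p = 1.0). Among marrow growth and niche factors, 5 of 12 were above and 3 below (Fisher's exact adjusted p = 0.497), led by Tgfb1 at 206 ± 11.96 CPM, Osm at 60.3 ± 16.6, Vegfa at 48.8 ± 3.48 and Apoe at 33.7 ± 9.55, with Cxcl16 at 0.108 ± 0.187 and Il18 at 1.86 ± 1.09.

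Between libraries, all 10 genes taken for their wide range were highest in replicate 1, and several are known to take up ribosomal RNA reads. Gm26917, a long non-coding RNA gene, was at 3459, 67.8 and 69.4 CPM in replicates 1, 2 and 3, and n-R5-8s1, a 5.8S ribosomal RNA copy, at 123, 8.44 and 2.95 CPM. Lars2 was at 910 CPM, 263 CPM and 77.3 CPM, Gm10800 at 513, 30.3 and 14.5, Gm23935 at 691, 211 and 65.2, and Gm15564 at 264, 75.7 and 24.3. Protein-coding genes of immune and progenitor cells with a wide range were the chemokine gene Ccl3 (42.1, 3.96 and 0.824 CPM) and Gata2, a transcription factor of progenitors, basophils and mast cells (51.7, 10.7 and 2.90 CPM). Gm10801 was at 43.3, 4.33 and 2.42 CPM, and Gm10717, at 27.8, 1.82 and 0.931 CPM, was called below 10 CPM in limma (adjusted p = 0.0398) but not in edgeR (0.900) or DESeq2 (0.956). Gm42418, chosen after its values were seen, took 1.31%, 0.487% and 0.136% of reads, mitochondrially encoded genes 0.802%, 0.591% and 0.800%, and ribosomal protein genes 2.20%, 1.82% and 1.504%.

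All 3 libraries held Y-linked transcripts. Eif2s3y was above 10 CPM at 43.9 ± 12.6 CPM, as was Ddx3y at 23.7 ± 10.3, Kdm5d was at 11.9 ± 3.18 and Uty at 6.76 ± 1.54 (SD, n = 3), and each was detected in every library. Xist was not listed here.

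**Figure D3:**
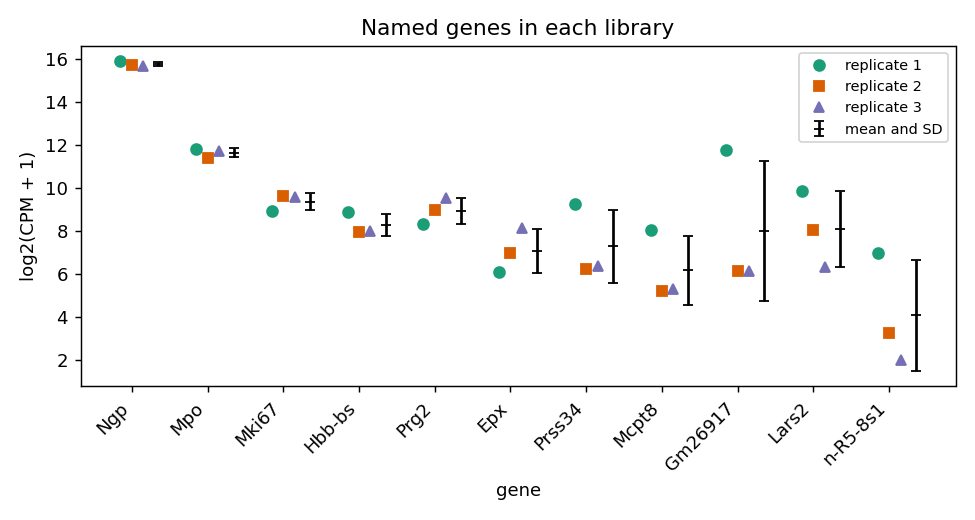
Level of 11 named genes, as log2(CPM + 1), in each of the 3 libraries (points), with the mean and SD beside them. Ngp and Mpo vary little between libraries, while Prss34 (596, 74.5 and 81.2 CPM) and Gm26917 (3459, 67.8 and 69.4 CPM) were higher in replicate 1.

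The common biological coefficient of variation was 0.326 over 11123 genes. Across genes, which are not independent replicates, Pearson correlations of log2(CPM + 1) were 0.971 between replicates 1 and 2, 0.956 between 1 and 3 and 0.978 between 2 and 3, with Spearman correlations of 0.975, 0.963 and 0.982. Among 7283 genes with a mean of at least 10 CPM, 111, 347 and 62 genes differed by more than 2-fold in these pairs. The chi-square of the reads per degree of freedom was 35.4, 70.3 and 83.6, computed to look for pairs that agree within the sampling noise of the reads, of which there were 0. It takes reads as independent molecules, so it says nothing on how far the cells differed. Between replicates 2 and 3, the squared coefficient of variation rose towards low levels as 0.512 divided by CPM, against 0.0257 divided by CPM for Poisson noise of the reads, over a constant of 0.0152. Genes at 0 reads numbered 538, 295 and 578 in replicates 1, 2 and 3, while 10285, 10311 and 10300 genes had at least 1 CPM.

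**Figure D4:**
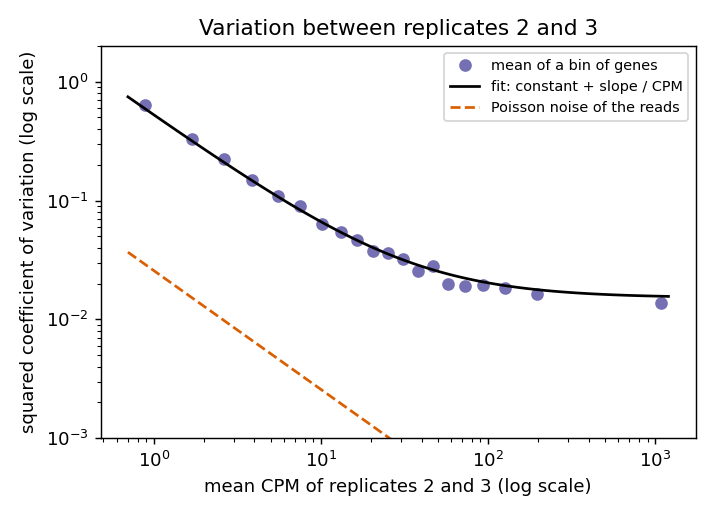
Squared coefficient of variation between replicates 2 and 3 (log axis) against mean CPM (log axis), as means of 20 bins of genes (points), with the fitted curve (solid) and the Poisson noise of the reads (dashed). The points follow a slope of 0.512 over CPM, above the 0.0257 over CPM of Poisson reads.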

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

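TMM scaling, edgeR on recovered reads, a pseudocount of 0.1 for the test of every gene, and library sizes without ribosomal DNA genes or without the late neutrophil list were alternatives chosen after seeing the data. Of 330 alternative values of the counts, lists, contrasts, ratios and spread, 307 kept the reported call or, where there is no call, stayed within a set range of the reported value. The 5 contrasts of macrophage with other lists were among these under each alternative run: without single libraries the late neutrophil contrast ranged from -9.36 to -9.13 and the primary granule contrast from -6.48 to -6.10. Those that did not pass the test moved by over 1.5 times, the monocyte contrast from 0.23 to 0.58, the erythroid from -1.08 to -0.47 and the B lymphoid from 0.28 to 0.81. Genes above 10 CPM ranged from 5884 to 6537 and genes below from 2423 to 3109 when single libraries were left out, and the common coefficient of variation from 0.260 to 0.371. No paired analysis was possible because the libraries form 1 group.

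With the level at 5 CPM, 1870 genes were below, the core macrophage list passed the threshold (33.3% above, adjusted p = 0.0417), and the calls of the complement and efferocytosis list (35.7%, 0.0689), the monocyte list (38.5%, 0.0822), the primary granule list (100%, 0.0822) and the lysosome list (88.2%, 0.137) were lost. At 20 CPM those of the dendritic list (0%, 0.0712) and the stromal list (0%, 0.214) were lost. Core macrophage genes also passed with DESeq2 size factors (26.7%, 0.049999) and TMM scaling (26.7%, 0.0499). Per kb of gene, the calls of complement and efferocytosis (21.4%, 0.0715), B lymphoid (38.5%, 0.437), dendritic (14.3%, 0.130), stromal (0%, 0.0770) and lysosome genes (82.4%, 0.0929) were lost. Against the tested genes alone the stromal list kept 0% above with an adjusted p of 0.165, by the loss of its untested members. Over single libraries left out, the share of complement and efferocytosis genes ranged from 0% to 35.7% and lost its call without replicate 3 (adjusted p = 0.339), and that of stromal genes was 0% in each case and lost its call without replicate 2 (0.0772) and replicate 3 (0.0605). With a pseudocount of 0.1 the log2 ratios to Cx3cr1 were 11.49 for Itgam, 6.99 for Adgre1 and 3.56 for Siglec1, by the smaller pseudocount under a gene near 0, and per kb that of Adgre1 was 4.75. Except where a construction is named, the cause was not tested.

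For 141 named genes, 1752 of 1814 alternative values kept their call. The lower and higher reference levels and CPM per kb of gene are not among these values. Calls of named genes that change under those settings are thus not counted here. Reversals were that of Cpa3 without replicate 1 (log2 level -0.079, leave-one-out range -0.079 to 1.02) and that of Gm10717 in DESeq2 (0.076, adjusted p = 0.956), where the cause was not tested. In edgeR 16 named genes lost their call, all below 10 CPM in limma. Depth limits replicate 1 most, where 10 CPM is 51.5 reads.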

Other observations

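Tests of cycling granulocyte precursors, of depth for Gm42418 and of counting noise for genes at 0 were chosen only after the result was seen, as was the test of lists other than the pooled macrophage lists for moving together. No biological explanation was tested against a second group, because the design has 1 group.

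Eosinophil genes and basophil and mast cell genes each shared a profile over the libraries. From each log2(CPM + 1) value, the median of its library over genes with a mean of at least 1 CPM was first taken off. Relative to each gene's own mean of these values, the 10 eosinophil genes deviated by -0.64 in replicate 1, 0.23 in replicate 2 and 0.41 in replicate 3. The 6 basophil and mast cell genes deviated by 1.27, -0.55 and -0.71. Hdc, the most abundant of the 6, did not follow its list, at 552, 609 and 675 CPM, and no test compared the profiles of both lists. Both lists deviated most in replicate 1, the shallowest library, which was also the highest in all 10 genes of wide range. Whether the profiles follow from how that library differs was not tested. A common profile held a share of 0.775 of the eosinophil genes' sum of squares between libraries and 0.756 of that of the basophil genes, against median shares of 0.0779 and 0.136 in random lists matched on level (random-list test, adjusted p = 0.0020 and 0.0090 over 20 lists). Monocyte genes (0.34, 0.07 and -0.41), niche factors (0.37, -0.03 and -0.34) and primary granule genes (0.22, -0.06 and -0.16) also shared a profile (random-list test, adjusted p = 0.0125, 0.0125 and 0.0328). Proliferation genes (deviations of 0.014 in replicate 1 and -0.014 in replicate 3, adjusted p = 0.975) and the late neutrophil list did not share a profile beyond chance (adjusted p = 0.742). On simulated lists of 12 genes this test called 5% of 200 random lists. It called 100% of 100 lists raised 2-fold in replicate 1 and lowered 2-fold in replicate 3. Smaller common shifts were not simulated.

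Neutrophil genes lay far above macrophage genes in cells gated on CD169 and F4/80, surface proteins that a sort would be thought to use to leave neutrophils out. Gene length is argued against, since the difference of medians kept 1.11 times its size per kb of gene (-10.11, permutation p = 1e-05, the smallest possible). Granulocyte precursors in cycle stay open: the proliferation list (Fisher's exact adjusted p = 0.00127) and the primary granule list (0.0290) both stood above the other genes, but these values raised the idea and so do not test it. The primary granule genes passed the test of a shared profile over libraries and the proliferation genes did not, but no test compared the profiles of these lists. A minority of macrophages, or macrophage fragments on other cells, is a candidate source of Vcam1, Slc40a1 and C1qa. These 3 genes were picked with their values known, and 20 of the 43 members of the 3 macrophage lists were below 10 CPM. Folr2 (0.0747 CPM) and Vsig4 (0.0647 CPM) had too few reads to be tested and are not counted among the 20. Over replicates 1, 2 and 3, C1qa fell (27.6, 16.3 and 12.3 CPM) while Slc40a1 changed little (175, 184 and 194 CPM). The TMM scaling factors of these libraries were 0.968, 0.971 and 1.06, so the small rise of Slc40a1 is not read as an opposite trend. The common profile of the 3 macrophage lists lay at percentile 93.2 of random lists (permutation p = 0.0683), between both bounds set in advance. Singly, the core macrophage list lay at percentile 2.5, complement and efferocytosis at 92.3 and erythroblastic island and iron recycling at 77.6, so this source cannot be told apart from genes that vary on their own.

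Gm42418, which overlaps a ribosomal DNA-like sequence on GRCm38 chromosome 17 (39846958 to 39848788), was at 13097, 4871 and 1358 CPM in replicates 1, 2 and 3. Depth is argued against, since replicates 2 and 3 differed 3.59-fold in Gm42418 and 1.07-fold in total reads. Ribosomal RNA carried into the libraries stays open, because of the 2 listed genes named in advance for such reads 1 followed the order of Gm42418 (Lars2, 11.8-fold range), while Gm26917 had a 51.0-fold range but a ratio of 0.977 between replicates 2 and 3. The ribosomal RNA copy n-R5-8s1 (123, 8.44 and 2.95 CPM) also followed that order, as did Gm23935 and Gm15564, but these were picked for their wide range. With the library size taken without Gm42418, Gm26917 and Lars2, 6559 genes were above and 3139 below 10 CPM.

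Genes without a single read were more frequent than counting noise gives. As a ratio the excess was largest in the deep libraries, where the number that counting noise gives is small. As a number of genes it was not larger in replicate 2, the deepest, than in replicate 1. In replicate 3, 418 of 11225 genes seen in the other libraries were at 0 where a Poisson draw at its depth gives 14.9, which is 28.0 times as many, and in replicate 2 the numbers were 135 and 6.27. Replicate 1, the shallow library, had 378 where such a draw gives 172, which is 2.20 times as many. Replicate 3 had 578 listed genes at 0 but 86 with 1 to 12 reads and 202 with 13 to 24, whereas replicate 1 had 538, 1321 and 987 and replicate 2, the deepest, had 295, 246 and 284, without the gap of replicate 3. These values are consistent with few RNA molecules behind the reads, since the variation between replicates 2 and 3 rose towards low levels with a slope 19.9 times that of Poisson reads (20.6 without the lowest bin), although differences between the animals or sorts at low genes would raise it too and were not tested. If so, a gene at 0 in a deep library may have been missed before sequencing, and the limits given for a count of 0 would be too low.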
